A study of Homo sapiens with 20 samples.

How the data were processed

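The series holds 20 expression arrays of HuES6, an established human embryonic stem cell line, 1 array for each pair of 5 BMP4 doses (0.25, 0.5, 1, 2 and 4 ng/ml) and 4 doses of CHIR00921 (0.25, 0.5, 1 and 2 µM; the compound's name is spelled as in the labels). Per the labels' protocols, cells grown in defined FTDA medium were replated on Matrigel in a medium free of serum and serum albumin. Both factors, with 10 ng/ml FGF2 in every sample, were present for the first 24 h, and insulin was given for the first day only. RNA was taken with Qiagen RNeasy columns and labelled with the Illumina TotalPrep kit, per the labels' protocols. The labels conflict on time: titles and growth protocol give 36 h, a time-point label gives days from 0 to 8, and the series' design text speaks of 2 weeks. The 36 h of the titles and protocol were used, and the labelled day was tested as a covariate.

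The deposited non-normalized table holds, for each of 47323 probes and each array, an intensity, the summarised probe brightness before background subtraction, and a detection p-value, which ranks the probe among negative control beads, per the file headers and the values. GenomeStudio is named in the submitters' processing notes, with its version not stated. A further value table deposited by the authors holds linear intensity values whose columns share a median of 4.53 and nearly 1 set of quantiles, so the authors subtracted a background and normalized between arrays by a method that is not stated. Its ranks match those of the non-normalized table (lowest Spearman's rho over arrays, 1), and it served as an alternative. No column of per-sample values was left unused.

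From the non-normalized intensity values, background was corrected by the normal-exponential model of limma 3.58.1 in R 4.3.3, with the background estimated from the detection p-values. An offset of 16 was added, and values were quantile-normalized and put on a log2 scale. A probe was kept when its detection p-value was under 0.05 on at least 4 of the 20 arrays, which left 24213 probes. Of the 47323 probes, 30113 had 1 gene symbol in the platform annotation, 8 had several, and 17202 were not listed there or had none. Entrez identifiers of 30074 of the 30113 matched the RefSeq table used for names, which changed 0 symbols; no coordinates were used. The kept probe with the highest mean represented each gene, which gave 13330 genes. Of the named genes, 71 had several kept probes, and 0 of these had probes called in both directions. The size of a slope often differed between probes, so it holds for the probe used: the lowest and highest were 0.028 and 1.13 for TFAP2A and 0.0088 and 0.48 for HOXC4 along BMP4, and 0.0098 and 0.82 for HOXC6 and −0.015 and 0.61 for HOXB6 along CHIR00921. LEFTY1 and LEFTY2, HSPA1A and HSPA1B, and the histone genes are near-identical copies whose probes may share signal, so their values are uncertain between copies.

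The design was fixed before the data were examined: 1 second-order response surface per gene over the 20 arrays, fitted in limma. Its 5 coefficients are the slope per doubling of BMP4, the slope per doubling of CHIR00921, their product (the interaction), and a square of each dose made orthogonal to its slope. A negative square means a curve that bends downward along the dose, whether or not it peaks inside the range. The fit left 14 residual degrees of freedom, to which limma's moderated test with an intensity trend added a median of 8.63. Tests were two-sided, with Benjamini-Hochberg adjustment over 13330 genes per coefficient and a threshold of 0.05. Further fits gave a BMP4 slope within each CHIR00921 dose (12 residual degrees of freedom) and a CHIR00921 slope within each BMP4 dose (10). With 1 array per dose pair there are no replicates. The residual therefore measures departures from a smooth surface, which mix array noise with any real bend the surface misses, and no p-value here compares a change with the spread between cultures. The number of arrays limits the precision. Errors printed as ± after a difference are SDs over the doses of the other factor (n = 4 or 5 dose levels, not replicates); those after a coefficient are standard errors.

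At the same stage 22 gene lists were fixed, among them markers of cell types the cultures could hold. Listed genes that failed the detection filter, such as 14 of the neuroectoderm list and 9 of the haematoendothelial list, or had no named probe were not tested. Each list was tested on each coefficient with limma's camera at a preset correlation of 0.01, adjusted over 110 tests, and again with an estimated correlation. Estimates ran up to 0.40 (primitive streak genes), and the preset gives much smaller p-values for such lists. Called lists printed with only the preset's adjusted p were also called by camera with the estimate, at adjusted p from 4.7e-04 to 0.044. Members were counted by their own adjusted p over all genes and adjusted over the list alone. Limma's fry, an alternative, tests whether a list's genes move on balance one way, and does not compare them with other genes. A list score per array is the mean of its members' log2 values, each minus that gene's mean over the arrays.

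The genes named were set by a rule. It takes the 10 largest positive and 10 largest negative slopes per factor among called genes, and the 5 largest per sign for the interaction and each square. It adds up to 4 members per list with the smallest adjusted p, any member of a list with at most 12 measured genes, and a fixed set of pathway and lineage genes. Of that set, PAX6 had 3 probes and was detected on 0 arrays, and TNNT2 had 0 probes with its name, so neither was tested. Genes outside the rule are said to be chosen after their values were seen.

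The fit was tested on simulated data with 13330 genes and known coefficients. A coefficient of 0.2 was called in 97.0% of the changed genes for the BMP4 slope, 91.0% for the CHIR00921 slope, 97.0% for the interaction, 100% for the BMP4 square and 86.6% for the CHIR00921 square. At 0.1 the shares were 56.7%, 31.3%, 67.2%, 67.2% and 28.4%, with 4 to 12 false calls per coefficient. Of simulated lists of 15 genes, the 1 shifted by 0.15 per doubling was called and 0 of 20 unshifted lists were. Simulated genes were independent of each other, so this could not show false calls that arise in correlated lists. Alternatives changed the background correction, offset, normalization, detection filter, probe choice, variance prior, array weights, dose scale, design and source table. Others added the labelled day, or an assumed 12-array chip as a block, or left out single arrays or all arrays of 1 dose. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.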

Results

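Gene expression was measured after 36 h of differentiation in human embryonic stem cells (line HuES6) that had received BMP4, a secreted ligand of the TGF-beta family that signals through SMAD proteins, and CHIR00921, the compound the series uses to drive WNT signalling. The question, from the series title, is which early fates follow from which doses of these 2 inputs. The 20 arrays form a full grid of 5 BMP4 doses and 4 CHIR00921 doses with 1 array per dose pair and no replicates. The grid has no array without a factor, so low means the lowest dose. Both factors were present for the first 24 h only, so levels at 36 h were read after the exposure had ended. Earlier responses of the factors' target genes were not measured. Between 20118 and 21870 probes were detected per array (42.5% to 46.2%), and median deposited intensities ran from 94.3 to 102. Pairwise correlations of log2 values across genes lay between 0.951 and 0.996, and the first component of the 13330 genes tested held 50.8% of the variance, the next 15.0% and the third 7.21%. A gene's difference is given below as the log2 level at the highest minus the lowest dose of a factor, averaged over the doses of the other. Its size is uncertain where arrays at the end with the lower level did not detect the probe. For a gene undetected on all arrays at that end, a fold given as at least starts from the lowest signal detected on each of those arrays, in place of any lower value.

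**Figure D1:**
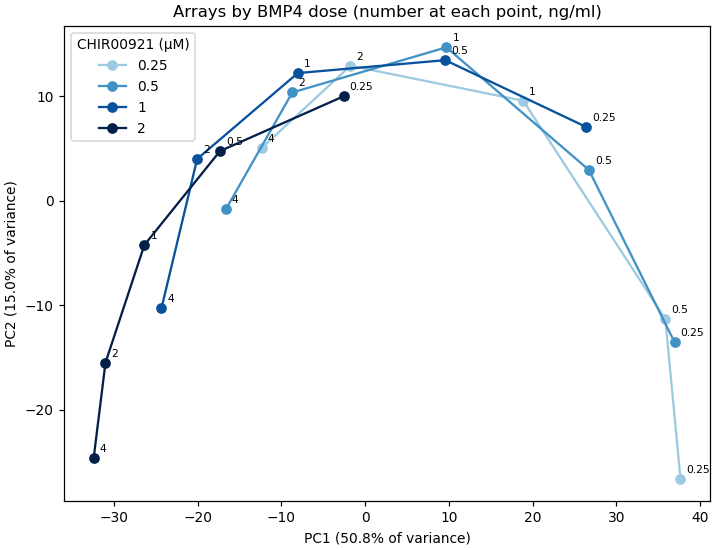
First against second principal component of the 13330 tested genes for the 20 arrays, in units of log2 signal, with a colour and line for each CHIR00921 dose (µM) and the BMP4 dose (ng/ml) written at each point. The components hold 50.8% and 15.0% of the variance, and both lowest doses and both highest doses lie at opposite ends of the first.

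Higher BMP4 turned down pluripotency factors and turned up transcription factors of mesoderm, trophoblast and amnion. SOX2, a core pluripotency factor, fell by 4.67 ± 1.50 from 0.25 to 4 ng/ml (n = 4 CHIR00921 doses, lower in 4 of 4), and NANOG, another, fell by 3.12 ± 0.62 (8.70-fold). HAND1, a transcription factor of lateral mesoderm and extraembryonic tissue, rose by 5.42 ± 1.71 (higher in 4 of 4). CDX2, which acts in trophoblast and posterior mesoderm, rose by 4.62 ± 1.55, and TFAP2A, a factor of amnion, trophoblast and surface ectoderm, by 4.28 ± 0.62. Along the BMP4 dose 1990 genes rose and 2085 fell in limma, 30.6% of those tested, of which 281 and 211 changed at least 2-fold over the grid.

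Among the 10 steepest rises were also MSX1 (5.30 ± 2.38), HAPLN1, a matrix link protein (5.03 ± 0.82), MESP1, a factor of early cardiac mesoderm (4.86 ± 2.91), CA12, a carbonic anhydrase (4.57 ± 0.54), the ligand gene WNT5A (4.09 ± 1.67), ATP12A, a proton pump subunit (4.05 ± 0.45), and the WNT agonist RSPO3 (3.84 ± 2.92, higher in 3 of 4). Steep falls besides SOX2 and NANOG were LEFTY1 and LEFTY2, inhibitors of NODAL signalling (−4.94 ± 2.35 and −3.58 ± 1.43), and the matrix gene THBS2 (−3.31 ± 0.80). FOXA2, a factor of endoderm and node, dropped by 3.19 ± 1.65, FGF8, a growth factor gene, by 2.84 ± 1.20 and the ligand gene GDF3 dropped by 2.83 ± 1.19. USP44 fell by 2.90 ± 0.88 and EDNRB fell by 2.78 ± 1.40. Slopes per doubling were 1.43 ± 0.10 for HAND1 (adjusted p = 1.1e-10), 1.13 ± 0.05 for TFAP2A (adjusted p = 2.1e-13; its 4 kept probes ran down to 0.028) and −1.22 ± 0.05 for SOX2 (adjusted p = 3.0e-14). POU5F1, the third core pluripotency factor, fell less, by 0.53 ± 0.11 (lower in 4 of 4; adjusted p = 2.1e-05). At 0.25 ng/ml HAND1, CDX2, CA12 and RSPO3 were detected on 2 of the 4 arrays, TFAP2A, HAPLN1 and ATP12A on 1 and WNT5A on 3. At 4 ng/ml LEFTY1 and FGF8 were detected on 2 and SOX2, LEFTY2, THBS2, GDF3 and USP44 on 3.

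Genes that SMAD proteins activate rose as a group. Of 14 measured BMP-SMAD targets 12 rose and 2 were not called, with the same counts adjusted over the list alone (camera adjusted p = 1.8e-14), among them ID4 (2.75 ± 0.60), MSX2 (2.47 ± 0.38), the decoy receptor gene BAMBI (2.36 ± 0.70) and ID3 (1.61 ± 0.99). In the pluripotency list 16 of 20 genes fell and 2 rose, or 16 and 3 adjusted over the list alone (adjusted p = 2.6e-09). The risers were LIN28B, an RNA-binding protein chosen after its values were seen, and SALL4, a zinc finger factor. TERF1, a telomere protein, fell by 1.31 ± 1.02 and DPPA4 by 1.03 ± 0.16. Of 18 trophoblast and amnion genes 10 rose, or 11 with 1 fall adjusted over the list alone (adjusted p = 2.6e-08). These included ISL1 (3.65 ± 0.78), TBX3 (2.96 ± 0.42) and GATA3, which was not detected at 0.25 ng/ml and was at least 1.73-fold higher at 4 ng/ml. A further 10 genes of this list failed the detection filter, and of its risers HAND1, ISL1, TBX3 and CDX2 also stand in the mesoderm lists, so the rise does not mark trophoblast or amnion alone. Of 18 cardiac and lateral mesoderm genes 14 rose and 1 fell, also adjusted over the list alone (adjusted p = 1.1e-09), among them PDGFRA (2.39 ± 1.28) and the apelin receptor gene APLNR (3.45 ± 3.10, higher in 3 of 4). KDR, the receptor of early blood and vessel progenitors, rose by 0.75 ± 0.64. At 0.25 ng/ml ID4 and MSX2 were detected on 1 of the 4 arrays, ISL1 on 2 and PDGFRA on 3.

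Presomitic and paraxial mesoderm genes also rose with BMP4, 12 of 18 with 2 falls, or 12 and 3 adjusted over the list alone (adjusted p = 7.8e-06), with WNT8A at 3.52 ± 1.37 (detected on 2 of the 4 arrays at 0.25 ng/ml) and WNT3A at 3.12 ± 1.86. Of 14 HOX genes, which set position along the body axis, 12 rose, also adjusted over the list alone (adjusted p = 4.3e-08, and adjusted p = 0.064 with an estimated correlation). Of 14 mesenchymal genes 10 rose and 1 fell, or 11 and 1 adjusted over the list alone (adjusted p = 4.3e-07, and adjusted p = 0.058 with an estimated correlation), for example COL5A1 (2.03 ± 1.27) and CDH2 (1.11 ± 0.64). Among 15 WNT-beta-catenin targets 7 rose and 2 fell, or 7 and 3 adjusted over the list alone (adjusted p = 0.0087, and adjusted p = 0.060 with an estimated correlation). LEF1, a nuclear partner of beta-catenin, rose by 2.79 ± 1.91 (detected on 2 of the 4 arrays at 0.25 ng/ml), while AXIN2 differed by 0.18 ± 0.16 and was not called (adjusted p = 0.28; higher in 3 of 4). Of 10 NODAL-SMAD2 targets 5 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.027, and adjusted p = 0.31 with an estimated correlation).

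Streak, endoderm and neural lists were mixed along BMP4. The primitive streak list, genes of the structure through which mesoderm and endoderm form, had 5 rises, such as TBXT at 3.26 ± 3.28 (higher in 3 of 4), and 4 falls, NODAL, FGF8, GSC and FOXA2, among 14 genes, with the same counts adjusted over the list alone (adjusted p = 0.25). NODAL is a TGF-beta family ligand, FGF8 a growth factor, and GSC and FOXA2 are factors of the anterior streak. Without the 4 arrays at 4 ng/ml the slope of GSC was 0.0093 and not called. The rise of MIXL1 turned to a called fall without those at 0.25 ng/ml (−0.16, adjusted p = 0.030) and to −0.070, not called, without those at 0.25 µM. Of 21 anterior streak and definitive endoderm genes 8 rose and 7 fell, or 9 and 7 adjusted over the list alone (adjusted p = 0.82); the median slope was 0.034, the mean −0.11 and the test's direction upward. Among the risers were GATA6 (1.45 ± 1.57, detected on 3 of the 4 arrays at 0.25 ng/ml) and SOX17, an endoderm factor (at least 1.22-fold). In the 10-gene neuroectoderm list 5 fell and 1 rose, or 6 and 1 adjusted over the list alone (adjusted p = 0.035, and adjusted p = 0.16 with an estimated correlation), with OTX2 at −1.76 ± 0.85. Of 13 epithelial genes 6 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.14), and of 7 haematoendothelial genes 2 rose and 2 fell in both counts adjusted over the list alone or over all genes (adjusted p = 0.53). The latter list's median slope was −0.017, its mean 0.085 and its test upward; its riser LMO2, a blood cell factor, gained 3.22 ± 0.71. No alternative moved the numbers of genes rising or falling with BMP4 by over 1.5 times.

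Higher CHIR00921 turned up HOX genes, CDX1, CDX2 and the ligand genes WNT3A and WNT8A, and turned down SOX2 and NANOG as BMP4 did. HOXB8 rose by 4.77 ± 2.85 from 0.25 to 2 µM (n = 5 BMP4 doses, higher in 5 of 5). It was undetected at 0.25 µM, and counted from the lowest detected signal there the rise was at least 23.1-fold. HOXB2 rose by 4.46 ± 1.11, CDX2 by 4.25 ± 1.55, CDX1, a posterior mesoderm factor, by 3.37 ± 2.09, and WNT3A, a ligand of the streak and tail bud, by 3.81 ± 1.80. NANOG fell by 3.13 ± 0.99 (8.74-fold) and SOX2 fell by 3.43 ± 1.76, each lower in 5 of 5. Along the CHIR00921 dose 2156 genes rose and 1781 fell, of which 179 and 109 changed at least 2-fold over the grid.

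The other steepest rises were MSX1 (4.31 ± 2.47), HOXB5 (3.91 ± 2.11), HAND1 (3.87 ± 1.90), RSPO3 (3.77 ± 2.93) and DLL1, a Notch ligand of paraxial mesoderm (3.59 ± 2.03). The other steepest falls were LEFTY1 (−3.84 ± 2.41), GDF3 (−3.10 ± 1.15), CFAP95 (−2.89 ± 1.02), LEFTY2 (−2.68 ± 1.52), the peptide hormone gene ADM (−2.39 ± 0.59), NODAL (−2.12 ± 1.52, lower in 4 of 5), VAT1L (−2.08 ± 0.54) and USP44 (−2.07 ± 0.83). Slopes per doubling were 1.54 ± 0.11 for HOXB8 (adjusted p = 1.6e-10), 1.30 ± 0.06 for WNT3A (adjusted p = 1.1e-13), 1.15 ± 0.05 for CDX1 (adjusted p = 9.6e-14) and −1.03 ± 0.08 for NANOG (adjusted p = 2.0e-09). POU5F1 fell by 0.82 ± 0.34 (lower in 5 of 5; adjusted p = 4.5e-08). TFAP2A, steep along BMP4, differed by 0.54 ± 0.66 from 0.25 to 2 µM (higher in 4 of 5) and passed the test with a slope of 0.19. At 0.25 µM HOXB2 was detected on 1 of the 5 arrays, CDX2, HOXB5, HAND1, RSPO3 and TFAP2A on 3 and CDX1 and ATP12A on 4. At 2 µM SOX2, LEFTY1 and GDF3 were detected on 2, and LEFTY2 and USP44 on 4.

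Of 15 WNT-beta-catenin targets 9 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0043). LEF1 gained 2.64 ± 1.98 and NKD1, a feedback inhibitor of the pathway, 1.64 ± 1.03. At 36 h, after the exposure had ended, AXIN2, another feedback inhibitor, rose with dose by 0.32 ± 0.25 (higher in 5 of 5, adjusted p = 0.0076). FZD7, a WNT receptor, fell by 1.20 ± 0.77, and SP5 was not called (−0.24 ± 1.57, adjusted p = 0.44, lower in 4 of 5). Of 14 HOX genes 12 rose, also adjusted over the list alone (adjusted p = 1.7e-11, and adjusted p = 0.033 with an estimated correlation), among them HOXA2 (1.84 ± 0.52). As along BMP4, this count depends partly on the detection filter. Of 18 presomitic and paraxial mesoderm genes 12 rose and 2 fell, also adjusted over the list alone (adjusted p = 1.3e-07), with WNT8A at 3.20 ± 1.26, DLL3 at 2.74 ± 1.46 and TBX6, a factor of presomitic mesoderm, at 1.30 ± 0.68. Of 18 cardiac and lateral mesoderm genes 15 rose (adjusted p = 6.1e-09), and of 14 mesenchymal genes 10 (adjusted p = 4.9e-08), both also adjusted over the list alone, with SNAI2, a repressor active in epithelial to mesenchymal transition, at 2.46 ± 0.92, CDH11 at 2.33 ± 1.18 and VIM at 1.36 ± 0.32. At 0.25 µM HOXA2 was detected on 2 of the 5 arrays, TBX6 and SNAI2 on 3, and LEF1 and WNT8A on 4.

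Pluripotency genes fell as a group along CHIR00921, 16 of 20 with 3 rises, or 17 and 3 adjusted over the list alone (adjusted p = 1.9e-14); PODXL dropped by 1.83 ± 0.41 and DNMT3B by 0.99 ± 0.23, and LIN28A, chosen after its values were seen, rose beside LIN28B and SALL4. BMP-SMAD targets rose in 10 of 14 with 2 falls, also adjusted over the list alone (adjusted p = 2.3e-06), with SMAD6 at 0.91 ± 0.33. Of 18 trophoblast and amnion genes 9 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.0015, and adjusted p = 0.061 with an estimated correlation); TFAP2C, a trophoblast factor, fell by 0.96 ± 0.37. Of 10 NODAL-SMAD2 targets 6 fell and 2 rose, or 7 and 2 adjusted over the list alone (adjusted p = 0.0056, and adjusted p = 0.22 with an estimated correlation). In the neuroectoderm list 6 of 10 fell and 1 rose (adjusted p = 0.0043, and adjusted p = 0.061 with an estimated correlation), and in the epithelial list 8 of 13 fell and 1 rose (adjusted p = 0.0023, and adjusted p = 0.25 with an estimated correlation), both also adjusted over the list alone. CLDN7, a tight junction protein, dropped by 0.73 ± 0.40. Primitive streak genes, 4 rises and 3 falls of 14, also adjusted over the list alone, were not called (adjusted p = 0.34), and neither were 21 anterior streak and endoderm genes, 6 rises and 8 falls, or 7 and 10 adjusted over the list alone (adjusted p = 0.40). In the haematoendothelial list 2 of 7 rose, also adjusted over the list alone (adjusted p = 0.82; median slope 0.060, mean −0.0063, test upward). Without the 5 arrays at 2 µM, 813 genes rose and 516 fell, and with an assumed chip as a block, which no label gives, 504 and 485. Counted over every kept probe, 2870 of 24213 probes fell, a count with another total than the 1781 of 13330 genes.

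**Figure D2:**
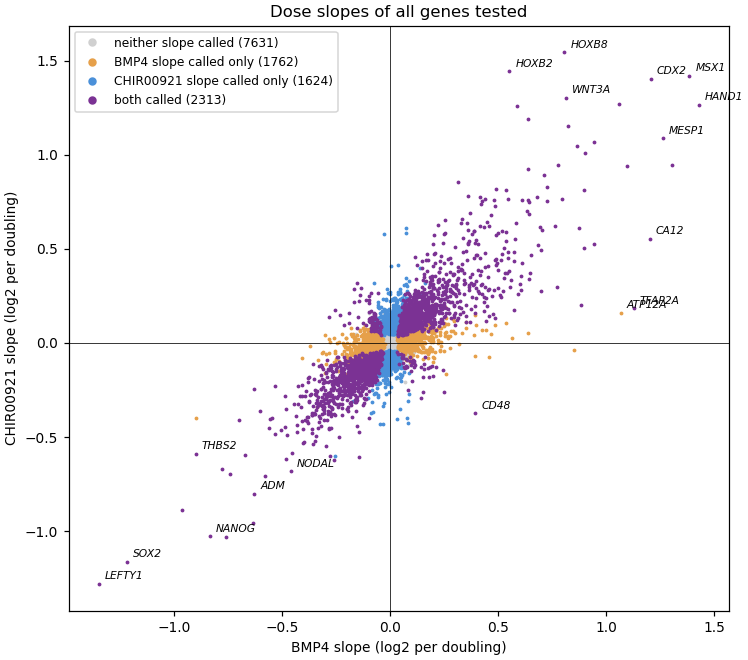
Slope per doubling of CHIR00921 against slope per doubling of BMP4 (log2 units) for each of the 13330 genes, coloured by which slopes were called. For 2313 genes both were called, and across genes the slopes correlate at r = 0.762.

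Most genes that answered both inputs moved the same way. Of 2313 genes called for both slopes, 1152 rose with both and 1049 fell with both, 95.2% in all, while 44 rose with BMP4 and fell with CHIR00921 and 68 did the opposite. Independent lists of these sizes would share 322, 279, 266 and 337 genes. HAND1, MSX1, CDX2 and RSPO3 are among the 10 steepest rises of both factors, and SOX2, NANOG, LEFTY1 and GDF3 among the steepest falls of both. BMP4 alone was called for 1762 genes, such as ATP12A (4.05 ± 0.45 along BMP4, 0.45 ± 0.67 along CHIR00921), and CHIR00921 alone for 1624, such as TFAP2C (−0.96 ± 0.37 along CHIR00921, 0.37 ± 0.69 along BMP4). Whether such slopes differ was not tested. Across genes, which are not independent replicates, the slopes correlated at r = 0.762 with a covariance of 0.00998. In 100 simulations of unchanged genes with noise independent between genes, r lay between −0.041 and 0.045 and the mean covariance was 2.5e-06. Noise shared between genes, which would widen that range, was not simulated.

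The next question is whether one factor's effect depends on the dose of the other. TBXT, the mesoderm factor of the primitive streak, climbed along BMP4 by 1.79 ± 0.20 per doubling with 0.25 µM CHIR00921 and had a slope of −0.06 ± 0.20 with 2 µM. Its lowest level, 5.03, lay at both lowest doses, and its highest, 12.33, at 1 ng/ml with 2 µM. EOMES, a factor of streak and endoderm, stood at 7.91 at both lowest doses, 12.43 at 0.5 ng/ml with 0.5 µM, and 9.04 at both highest. HOXB8 went the other way: its BMP4 slope was 0.03 ± 0.18 at 0.25 µM and 1.79 ± 0.18 at 2 µM. It was undetected on every array at 0.25 µM, so its flat slope there reflects the detection floor. In all, 1517 genes had an interaction (11.4%), 803 negative and 714 positive.

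The largest negative product coefficients were those of DKK4, a secreted WNT antagonist (−0.88 ± 0.15, adjusted p = 3.5e-04), CER1, a secreted antagonist of NODAL, BMP and WNT (−0.72 ± 0.07, adjusted p = 6.0e-07), APLNR (−0.63 ± 0.05, adjusted p = 4.5e-08), TBXT (−0.62 ± 0.04, adjusted p = 1.7e-09) and MESP1 (−0.61 ± 0.08, adjusted p = 1.6e-05). The largest positive ones were HOXB8 (0.61 ± 0.07, adjusted p = 5.2e-06), HOXC6 (0.49 ± 0.08, adjusted p = 1.3e-04), HOXC4 (0.48 ± 0.07, adjusted p = 3.7e-05), GADD45G (0.46 ± 0.04, adjusted p = 2.0e-08) and LINGO1 (0.45 ± 0.04, adjusted p = 2.0e-07). GADD45G was highest with both factors high (7.83) and next with both low (7.25), and was undetected on several arrays between. SOX2 had a positive coefficient (0.33 ± 0.05), its fall along BMP4 being −1.63 ± 0.13 per doubling at 0.25 µM and −0.63 ± 0.13 at 2 µM, where it neared the lowest value of any probe, 4.09.

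Streak and WNT target genes lay mostly on the negative side and HOX genes on the positive side. Of 14 primitive streak genes 11 had a negative interaction, also adjusted over the list alone (adjusted p = 2.7e-19, and adjusted p = 0.013 with an estimated correlation). Among them were LHX1 (−0.59), MIXL1 (−0.56), EOMES (−0.54), CDX1 (−0.45), NODAL (−0.28) and SP5 (−0.29). Of 15 WNT-beta-catenin targets 10 were negative, also adjusted over the list alone (adjusted p = 8.5e-12), for example DKK1 (−0.56) and LEF1 (−0.41). Of 18 cardiac and lateral mesoderm genes 7 were negative, or 8 adjusted over the list alone (adjusted p = 3.2e-06). Of 14 HOX genes 10 were positive, or 12 with 1 negative adjusted over the list alone (adjusted p = 5.8e-12, and adjusted p = 0.031 with an estimated correlation). HOXB8 was detected on 8 of the 20 arrays and HOXB7 and HOXC4 on 5, though HOXC6 on 20. A detection floor at low doses would also give positive coefficients, and this was not tested for the interaction. Of 20 pluripotency genes 10 were positive and 2 negative, or 11 and 2 adjusted over the list alone (adjusted p = 5.6e-05), for example PRDM14 (0.38) and TERF1 (0.22). Calls for the anterior streak list (8 negative and 2 positive of 21, adjusted p = 2.5e-04), the presomitic list (6 and 2 of 18, adjusted p = 0.0011), the mesenchymal list (6 and 2 of 14, adjusted p = 0.0042) and the epithelial list (2 positive of 13, adjusted p = 0.032) were lost: adjusted p = 0.061, adjusted p = 0.11, adjusted p = 0.25 and adjusted p = 0.44 with an estimated correlation, in that order. Adjusted over the list alone these counts were 10 and 2, 7 and 2, 8 and 3, and 3 positive. The other 13 lists were not called (adjusted p from 0.083 to 0.93); among them the BMP-SMAD list had a positive median (0.017) and a negative mean (−0.028) and test. Without the array at 0.25 ng/ml with 2 µM 913 genes had an interaction, and without all arrays at 2 µM, where the coefficients of CDX2 and HAND1 turned positive, 587 did. Without the arrays at 0.25 µM the count was 807, without those at 0.25 ng/ml 958, without those at 2 ng/ml 975, and with doses on a linear scale 199.

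**Figure D3:**
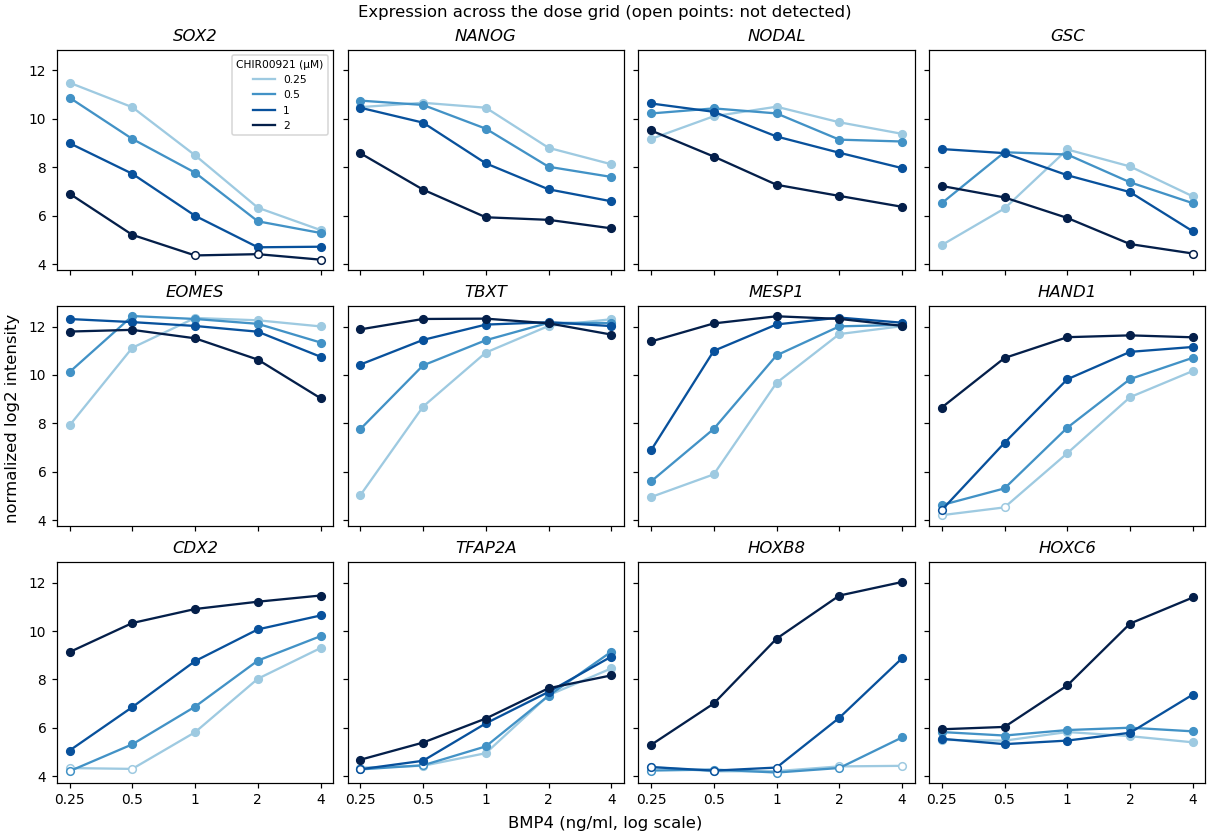
Normalized log2 signal of 12 genes against BMP4 dose (ng/ml, log axis), 1 line per CHIR00921 dose and 1 point per array, open where the probe was not detected. EOMES peaks at 12.43 with 0.5 ng/ml and 0.5 µM, and HOXB8 reaches 12.03 at both highest doses.

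Some genes were higher at a dose pair between the low and the high corner of the grid than at either corner. DKK4 stood at 4.26 at both lowest doses, 10.82 at 0.5 ng/ml with 1 µM, and 4.23 at both highest, undetected at both ends. CER1 went from 6.11 to 10.23 and down to 4.26, and GSC, a factor of the organizer and anterior streak, from 4.78 to 8.75 at 0.25 ng/ml with 1 µM and down to 4.43. MIXL1, a factor of mesendoderm, went from 5.82 to 11.54 at 1 ng/ml with 0.25 µM and then 9.32. For 47 genes, the mean of 4 middle arrays was at least 2-fold above the means of the 3 arrays in the low corner and the 3 in the high corner of the grid; this count was chosen after the values were seen.

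Along BMP4 599 genes had a called curvature, 329 negative (bending downward) and 270 positive. The sign gives the bend and not the place of the peak. With 0.25 µM CHIR00921, MESP1, whose square is negative, climbed to its highest value there at 4 ng/ml (12.01). The largest negative coefficients belonged to CALCR, the calcitonin receptor (−0.46 ± 0.07, adjusted p = 2.7e-04), APLNR (−0.43 ± 0.05, adjusted p = 2.2e-05), LHX1 (−0.41 ± 0.05, adjusted p = 3.0e-05), IRX3 (−0.41 ± 0.07, adjusted p = 0.0013) and MESP1 (−0.37 ± 0.08, adjusted p = 0.0047). The largest positive ones were HPGD, which degrades prostaglandins (0.46 ± 0.04, adjusted p = 2.4e-07), the kinase gene SGK1 (0.35 ± 0.04, adjusted p = 6.1e-06), the chemokine gene CXCL12 (0.32 ± 0.06, adjusted p = 0.0044), RPRM (0.30) and TRIML2 (0.29). With 0.5 µM CHIR00921, HPGD was at 5.68 at 2 ng/ml and 8.70 at 4 ng/ml. It was detected on 11 of the 20 arrays, with a lowest value of 4.34, so the detection floor may add to its bend. Of 14 primitive streak genes 10 were negative, also adjusted over the list alone (adjusted p = 2.3e-16, and adjusted p = 0.017 with an estimated correlation). Of 15 WNT targets 8 were negative, or 10 with 2 positive adjusted over the list alone (adjusted p = 9.2e-08). Positive were 5 of 13 epithelial genes, or 8 adjusted over the list alone (adjusted p = 1.8e-09), 6 of 18 trophoblast and amnion genes, or 7 adjusted over the list alone (adjusted p = 1.6e-06), and 6 of 20 pluripotency genes, or 10 adjusted over the list alone (adjusted p = 1.1e-05). Of 7 further lists called along BMP4, the mesenchymal list (4 negative and 1 positive of 14), the cardiac list (4 and 1 of 18), the presomitic list (5 negative of 18) and the anterior streak list (6 and 1 of 21) shifted downward, as did the glycolysis list (3 and 1 of 19). The BMP-SMAD list (3 positive of 14) and the HOX list shifted upward, the latter with 0 of 14 genes called. Adjusted over the list alone the counts were 7 and 2, 8 and 1, 8 and 2, 7 and 1, 7 and 1, 5 positive and 1 positive. With an estimated correlation none was called (adjusted p = 0.13, 0.090, 0.090, 0.22, 0.17, 0.14 and 0.37, in that order). Without the 4 arrays at 4 ng/ml 15 genes had a BMP4 curvature, without those at 1 ng/ml 146, at 2 ng/ml 332 and at 0.25 ng/ml 281, and without those at 0.5 or 1 µM 177 or 263. Without the single array at 4 ng/ml with 0.5 µM the count was 391.

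Along CHIR00921 184 genes curved, 67 upward and 117 downward. HOXB8 (0.81 ± 0.12, adjusted p = 0.0014), HOXB2 (0.67 ± 0.10, adjusted p = 0.0021), HOXB5 (0.63 ± 0.10, adjusted p = 0.0021), HOXC6 (0.52 ± 0.12, adjusted p = 0.036) and HOXC4 (0.49 ± 0.11, adjusted p = 0.026) led the upward side. On it were 11 of 14 HOX genes, or 12 adjusted over the list alone (adjusted p = 3.4e-21, and adjusted p = 0.0079 with an estimated correlation). With 4 ng/ml BMP4, HOXB8 went through 4.43, 5.60, 8.88 and 12.03 over the 4 CHIR00921 doses and HOXC6 through 5.40, 5.86, 7.38 and 11.39. Of the 11 HOX genes, 2 were undetected on all 10 arrays at 0.25 and 0.5 µM. Median, mean and test differed in sign for the BMP4 squares of the contractile and p53 lists and the CHIR00921 squares of the WNT, trophoblast, haematoendothelial and p53 lists, none of them called. The largest negative coefficients were CER1 (−0.70 ± 0.12, adjusted p = 0.0037), CALCR (−0.57 ± 0.12, adjusted p = 0.013), GSC (−0.55 ± 0.13, adjusted p = 0.028), CD48, a surface protein of blood cells (−0.48 ± 0.11, adjusted p = 0.028), and NODAL (−0.42 ± 0.07, adjusted p = 0.0034). Of 21 anterior streak genes 4 were negative, or 7 adjusted over the list alone (adjusted p = 2.6e-06), of 20 pluripotency genes 3, or 8 with 2 positive adjusted over the list alone (adjusted p = 0.0024), and of 14 primitive streak genes 5, or 9 adjusted over the list alone (adjusted p = 3.1e-09, and adjusted p = 0.061 with an estimated correlation). Without the 5 arrays at 2 µM, 0 genes had a CHIR00921 curvature in limma (549 at an unadjusted p under 0.05) and the coefficient of HOXC6 was −0.12; any other single dose left out, save 0.25 or 4 ng/ml, gave 4 to 71. Leaving out the array at both highest doses gave 386 genes and that at 4 ng/ml with 0.25 µM 81, while the labelled day as a covariate gave 26, the assumed chip 82 and no detection filter 99.

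Seen within single doses, each factor had the fewest called genes at the highest dose of the other. The BMP4 slope was called for 1952 genes at 0.25 µM CHIR00921, 1646 at 0.5 µM, 1287 at 1 µM and 824 at 2 µM. The CHIR00921 slope was called for 1266, 1402, 1060, 539 and 357 genes from 0.25 to 4 ng/ml BMP4. LEF1 rose along BMP4 by 1.22 ± 0.14 per doubling at 0.25 µM (adjusted p = 1.1e-05) and had a slope of 0.03 ± 0.14 at 2 µM, where it was not called. TFAP2A rose along BMP4 at every CHIR00921 dose, with slopes from 0.92 to 1.26. NODAL fell along BMP4 by 0.79 ± 0.10 per doubling at 2 µM (adjusted p = 9.4e-05) and differed by 0.02 ± 0.10 at 0.25 µM. The change in the number of calls was not tested itself. The interaction tests the slopes. These counts rest on single end arrays: without the 2 µM array of the same BMP4 dose the CHIR00921 slope was called for 17 genes at 1 ng/ml and 0 at 2 and 4 ng/ml in limma (1343 and 742 at an unadjusted p under 0.05). Without the array at 0.25 ng/ml with 0.25 µM the BMP4 slope at 0.25 µM was called for 1053 genes.

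The gene lists scored highest at several different dose pairs, some of which lists shared. The pluripotency score was highest at both lowest doses (1.14) and lowest at both highest (−0.69). NODAL targets (1.29) and anterior streak and endoderm genes (0.56) were highest at 0.25 ng/ml with 1 µM, WNT targets at 0.25 ng/ml with 2 µM (0.54), and primitive streak genes at 0.5 ng/ml with 1 µM (1.03, against −2.63 at both lowest doses). Cardiac (1.02), presomitic (1.19) and mesenchymal genes (0.81) were highest at 1 ng/ml with 2 µM. Trophoblast and amnion genes were highest at 4 ng/ml with 1 µM (1.05), haematoendothelial genes at 4 ng/ml with 0.25 µM (0.28), and HOX genes (2.94) and BMP-SMAD targets (1.20) at both highest doses. These places rest on single arrays and were not tested.

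**Figure D4:**
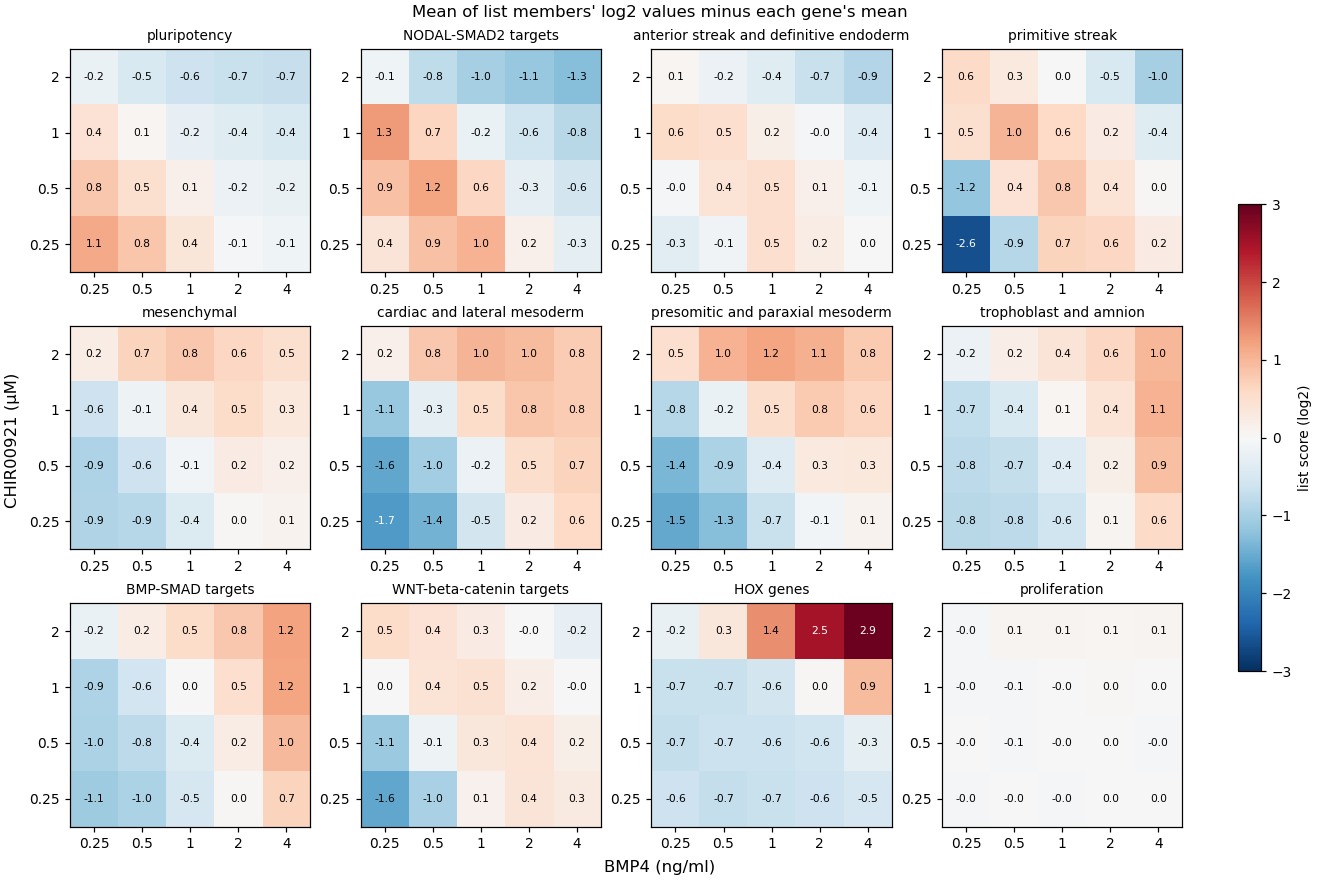
List scores per dose pair for 12 gene lists, BMP4 dose (ng/ml) across and CHIR00921 dose (µM) up, each cell the mean over members of log2 value minus the gene's mean. The primitive streak score peaks at 1.03 with 0.5 ng/ml and 1 µM, and the HOX score at 2.94 with both highest doses.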

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

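Tests of the arrangements of the doses over the arrays were planned; all tests of a technical explanation in this part were chosen after the results were seen. The genes and the pattern of genes given here were picked out because the effect of one factor differed with the dose of the other by the interaction test in limma.

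A BMP4 by CHIR00921 interaction was called for 1517 genes. Values are given for the called genes among the 5 largest per sign, the fixed pathway and lineage set, and the named members of lists whose interaction held with an estimated correlation. Negative product coefficients were −0.88 for DKK4, −0.72 for CER1, −0.63 for APLNR, −0.62 for TBXT, −0.61 for MESP1, −0.59 for LHX1, −0.56 for MIXL1, −0.56 for DKK1, −0.54 for EOMES, −0.47 for GSC, −0.45 for CDX1 and −0.41 for LEF1. Smaller ones were −0.29 for SP5, −0.29 for HAND1, −0.28 for NODAL, −0.25 for MYL7, −0.25 for CDX2, −0.19 for PDGFRB and −0.18 for NKD2. Positive coefficients were 0.11 for JARID2, 0.15 for HOXD1, 0.22 for TERF1, 0.33 for SOX2, 0.38 for HOXB7, 0.38 for PRDM14, 0.40 for HOXB6, 0.45 for LINGO1, 0.46 for GADD45G, 0.48 for HOXC4, 0.49 for HOXC6 and 0.61 for HOXB8.

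The counts of genes were set against chance arrangements, and in each case 1 of 100 arrangements, the real one, reached the real count. With 100 arrangements no share under 1 of 100 can be seen. With BMP4 doses permuted within each CHIR00921 dose, the highest other counts were 711 rising and 695 falling genes, against 1990 and 2085. With CHIR00921 doses permuted within each BMP4 dose they were 423 and 363, against 2156 and 1781. With residuals permuted around the fit without the tested term, the highest other counts were 0 genes for the interaction (real 1517), 1 for the BMP4 curvature (real 599) and 73 for the CHIR00921 curvature (real 184). The last margin depends on the setting. The CHIR00921 curvature count was 26 with the labelled day as a covariate and 0 without the arrays at 2 µM. The arrangements were not repeated in those settings.

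The first pattern weighed is the negative interaction of primitive streak genes (11 of 14), the genes of early mesoderm and endoderm that stopped rising or fell where both factors were high. Probes near the top of the scale could give this, but a ceiling can level a gene off and not lower it, and along BMP4 at 2 µM the median slope of the 11 genes was −0.45 per doubling (SD over genes 0.35; 9 below 0, of which 1 was called alone). For TBXT, MESP1 and CDX1, the 3 genes within 2-fold of their highest array, the gap between their median highest value and the highest value of any probe was 1.58, and a ceiling cannot be told apart from a plateau of the cells because no brighter standard for these probes exists here. A falling share of undifferentiated cells alone would put the streak genes' highest values at the dose pair with the lowest pluripotency score, 4 ng/ml with 2 µM, where 0 of the 11 genes had theirs. Both tests use the 11 genes chosen by the interaction in these same arrays, which favours such outcomes. The SD over genes is also no error of the median slope, so neither explanation is excluded. A response of the cells to both doses, which the design varies, stays open and untested.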

How the results depend on the processing

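Directions and calls were mostly kept. Of 7121 comparisons of named genes with an alternative, 6659 kept direction and side of the threshold, 396 lost the call, 59 gained it and 7 turned direction; of 4444 comparisons of lists the numbers were 4212, 171, 60 and 1. From the authors' deposited values, 176 of 178 named results and 110 of 110 list results were kept, and 2 named results gained a call. The counts rising and falling with BMP4 stayed between 1358 and 2654 and between 1413 and 2980. Some settings tested other numbers of genes, or probes in place of genes, so these counts do not share a total. With an estimated correlation, the only setting changed, 27 of 58 list shifts were called. The estimates reached 0.40 for primitive streak, 0.35 for HOX and 0.33 for epithelial genes, against the preset 0.01. Fry, which does not compare lists with other genes, lost 6 list calls and gained 15. Leaving out arrays leaves fewer samples and often a shorter dose range; beyond that, the cause was not tested for any change below.

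With every kept probe counted on its own 2870 of 24213 probes fell with CHIR00921, which is not a rise over 1781 of 13330 genes, since the totals differ. With an assumed chip as a block, largely confounded with CHIR00921 dose, 504 genes rose, 485 fell and 82 curved with CHIR00921. With the labelled day as a covariate 26 curved with CHIR00921, and with no detection filter 99 did and 348 had a CHIR00921 slope at 2 ng/ml. With doses on a linear scale 199 genes had an interaction.

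Interaction counts were 958 without the arrays at 0.25 ng/ml BMP4, 975 without 2 ng/ml, 807 without 0.25 µM CHIR00921 and 587 without 2 µM. BMP4 curvature counts were 281, 146, 332 and 15 without 0.25, 1, 2 and 4 ng/ml, and 177 and 263 without 0.5 and 1 µM. CHIR00921 curvature counts were 48, 71 and 35 without 0.5, 1 and 2 ng/ml, and 7, 65, 4 and 0 (549 at an unadjusted p under 0.05 in limma) without 0.25, 0.5, 1 and 2 µM. Without 2 µM 813 genes rose and 516 fell with CHIR00921. The BMP4 slope of MIXL1 was −0.16, a called fall, without 0.25 ng/ml and −0.070 without 0.25 µM, and that of GSC 0.0093 without 4 ng/ml. Without 2 µM the CHIR00921 slope of GSC was 0.27, the product coefficients of CDX2 and HAND1 were 0.037 and 0.038, the CHIR00921 curvature of HOXC6 was −0.12, and the median CHIR00921 slope of glycolysis genes was 0.00995.

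Leaving out each array in turn gave 913 to 1582 genes with an interaction, 391 to 771 with a BMP4 curvature and 81 to 386 with a CHIR00921 curvature. The BMP4 slope was called for 1053 to 2008 genes at 0.25 µM, 748 to 1710 at 0.5 µM, 609 to 1371 at 1 µM and 321 to 907 at 2 µM. The CHIR00921 slope was called for 527 to 1497 genes at 0.25 ng/ml, 653 to 1537 at 0.5 ng/ml, 17 to 1289 at 1 ng/ml, 0 to 874 at 2 ng/ml and 0 to 530 at 4 ng/ml. The lowest counts came without an end array of the same dose, which leaves a shorter dose range. Signal over background limits genes near the lowest log2 value of 4.09: the size of falls to it and rises from it is uncertain.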

Other observations

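The histone counts, the overlap behind them and every test of an explanation in this part were chosen after the results were seen; the lists and covariates were planned. For the genes that peak between the corners, the count was known when its bound was set, and the test of agreeing slopes was added after it.

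Genes of glycolysis and the hypoxia response fell with BMP4: 16 of 19, also adjusted over the list alone (adjusted p = 1.8e-11, and adjusted p = 0.0079 with an estimated correlation). ADM, a vasodilator peptide induced by low oxygen, fell by 2.43 ± 0.36 from 0.25 to 4 ng/ml (lower at 4 of 4 CHIR00921 doses), the enolase gene ENO2 by 1.48 ± 0.35 and the aldolase gene ALDOC by 0.80 ± 0.10. Along CHIR00921 9 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.0060, and adjusted p = 0.19 with an estimated correlation). Without the arrays at 2 µM this list's median CHIR00921 slope was 0.00995. Of 13 cholesterol synthesis genes 8 fell with BMP4, also adjusted over the list alone (adjusted p = 0.0083, and adjusted p = 0.25 with an estimated correlation), with HMGCS1, an early enzyme of the pathway, at −0.58 ± 0.16. Along CHIR00921 2 fell and 1 rose, or 3 and 1 adjusted over the list alone (adjusted p = 0.21). Of 13 unfolded protein and heat shock genes 7 rose and 2 fell with BMP4, also adjusted over the list alone (adjusted p = 0.0092, and adjusted p = 0.058 with an estimated correlation), among them ASNS, an asparagine synthetase induced by amino acid stress (1.11 ± 0.37). Along CHIR00921 3 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.88; median slope 0.024, mean −0.0012, test upward), and the stress factor ATF3 fell by 0.66 ± 0.31.

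Lists for dividing, dying and other cells were not called as groups for the slope along either factor. Of 22 proliferation genes 7 rose and 2 fell with BMP4, or 11 and 2 adjusted over the list alone (adjusted p = 0.14), 5 rose and 1 fell with CHIR00921, also adjusted over the list alone (adjusted p = 0.25), and the score spanned 0.148 over the grid. Of 13 p53 and apoptosis genes 2 rose and 5 fell with BMP4 (adjusted p = 0.44) and 4 rose with CHIR00921 (adjusted p = 0.074), both also adjusted over the list alone. CDKN1A, an inhibitor of the cell cycle, rose by 0.75 ± 0.68 with CHIR00921 (higher in 4 of 5) and PHLDA3 fell by 0.60 ± 0.10 with BMP4. Of 7 neural crest genes 3 rose and 1 fell with BMP4 (adjusted p = 0.64) and 1 rose and 1 fell with CHIR00921 (adjusted p = 0.85), both also adjusted over the list alone. Of 10 contractile genes of heart muscle 2 rose and 2 fell with BMP4 (adjusted p = 0.67) and 3 fell with CHIR00921 (adjusted p = 0.30), both also adjusted over the list alone; MYH6 was not called for either slope. Of 12 housekeeping genes 1 rose and 5 fell with BMP4 (adjusted p = 0.096) and 4 fell with CHIR00921 (adjusted p = 0.14), both also adjusted over the list alone. ACTB was not called along either factor (−0.069 ± 0.17 and −0.0063 ± 0.14), GAPDH fell by 0.17 ± 0.10 with BMP4, and B2M, part of surface MHC class I, rose by 1.00 ± 0.26. Along CHIR00921 the squares of presomitic, cardiac, mesenchymal, BMP-SMAD, NODAL, neuroectoderm, proliferation and glycolysis lists were also called, of which glycolysis alone held (adjusted p = 0.014 with an estimated correlation). For the others the result was adjusted p = 0.26, 0.22, 0.22, 0.16, 0.14, 0.17 and 0.22 with an estimated correlation, in that order. Few members were called: 1 positive and 1 negative presomitic gene, 1 positive cardiac, 2 positive mesenchymal, 2 negative NODAL, 3 negative neuroectoderm and 4 negative glycolysis genes, and 0 of the BMP-SMAD and proliferation lists. Adjusted over the list alone, 5 presomitic genes were positive and 2 negative, and 5 mesenchymal genes positive and 1 negative. In the same count 1 NODAL gene was positive and 3 negative, and 1 neuroectoderm gene positive and 4 negative. Glycolysis then had 8 negative genes, the cardiac and BMP-SMAD lists 1 positive each and the proliferation list 0.

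Some genes moved in opposite directions, such as NPPB, a natriuretic peptide (1.00 ± 0.83 along BMP4 and −0.78 ± 0.84 along CHIR00921), and CD48 (1.52 ± 1.97 and −1.30 ± 2.15). NPPB was detected on 4 of 5 arrays at 2 µM, and CD48 on 3 of 4 at 0.25 ng/ml and 4 of 5 at 0.25 µM. Of 68 genes that fell with BMP4 and rose with CHIR00921, 12 were histone genes of 47 measured, a class noticed among these genes, so no test of this count is given. Of the 47 histone genes, whose probes can share signal between near-identical copies, 17 rose along CHIR00921, and 17 fell and 1 rose along BMP4. Unadjusted camera p-values along CHIR00921 and BMP4 were p = 1.1e-04 and p = 0.0206 at the preset correlation. With an estimated correlation they were p = 0.0624 and p = 0.246. The class was picked from these same data, so no conclusion is drawn from these p-values. The labelled day was called for 0 genes in limma beside the doses (460 at an unadjusted p under 0.05) and 0 alone (515). The assumed chip was called for 0 genes in limma (918 at an unadjusted p under 0.05), and its correlation with log2 CHIR00921 dose over the arrays was −0.82.

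The second pattern weighed, a result of the squared term, is the upward curve of HOX genes along CHIR00921 (11 of 14), which rests on the arrays at 2 µM, without which 0 genes curved in limma (549 at an unadjusted p under 0.05). A detection floor that hides the lower steps cannot be told apart from a real bend: in the 7 genes detected at 0.5, 1 and 2 µM with 4 ng/ml, the last step exceeded the one before by a mean of 0.55 (SD 0.97; exact one-sided sign-flip p = 0.0938, smallest possible 0.0078). Among them HOXC6 stepped by 1.52 and then 4.01, and HOXB8 by 3.27 and then 3.15. A steeper response of HOX genes at high dose, which the design varies, stays open and untested beyond this.

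The third pattern weighed is the likeness of BMP4 and CHIR00921 slopes across genes. Quantile normalization is not its source, since after median scaling r was 0.762. The 2 factors run in opposite directions along the sample number, so a drift along it alone would give an r below 0, where 0.762 was found. The arrays are numbered in blocks of equal CHIR00921 dose, from 2 µM at sample 1 to 0.25 µM at sample 20. A drift beside the dose effects is therefore largely confounded with the CHIR00921 slopes and was not tested. If both factors only changed the shares of 2 fixed cell states, genes with agreeing slopes would all lie further along on the same arrays. Of 361 that differed by over 3 standard errors between arrays high in BMP4 and arrays high in CHIR00921, 3.60% went the smaller way (13 against 348). These genes were chosen for agreeing slopes, and a stronger effect of BMP4 would give the same skew, so this test cannot decide. The idea of 2 fixed states forbids genes that peak between the corners of the grid, and 45 genes were at least 2-fold and over 3 standard errors above both corners on the middle arrays. These genes were picked for their middle peaks in these same arrays, and the count was known when its bound was set. The count therefore cannot decide for or against shares of only 2 fixed states. Of the 47 at least 2-fold above, 7 have agreeing slopes. These tests cannot separate changing shares of 2 fixed states from a sorting of cells into more than 2 states. Nor can they separate either from 1 shared course of all cells whose speed both factors set.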
